A study of Drosophila melanogaster with 2 samples.

How the data were processed

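Binding of Atonal fused to enhanced GFP was measured by ChIP-seq in whole Drosophila melanogaster embryos aged 0 to 18 h, in 2 biological replicates, per the labels. Chromatin was sheared by sonication to 200 to 800 bp and precipitated with an antibody against GFP, per the labels. Both samples form 1 group, and their replicate numbers are those of the labels.

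The authors deposited 8 peak lists on dm6: for each replicate and for the 2 ways of combining them, a list ranked by the irreproducible discovery rate (IDR) and a thresholded list. The lists of a replicate were derived from its own alignment and the combined lists from both, per the accompanying text files. The aligner, the peak caller and their versions are not given in the sources used here. Per the same text files, every list was also derived from 1 further file common to all, and each thresholded list from another. The nature of these is not given in the sources used here, so whether peaks were called against a control is unknown, and no control was analysed here. The signal of each peak is the authors' deposited value on a scale that is not given in the sources used here, and it was used only to rank, filter or describe peaks within a list. The ranked lists also carry the -log10 of the global IDR, as deposited by the authors. In the list that pairs the replicates, columns of signal for each replicate are given without naming which is which. When tested on the files, every peak of the conservative thresholded list was in the ranked list pairing the replicates with a global IDR of at most 0.01, and 124 further ranked peaks past that value were not in it. They were left out of the background. No thresholded list had peaks above that rate, so the planned stricter threshold was replaced by the strongest 50% by signal, as had been laid down. The files hold no read counts, so the depth of each replicate is unknown and no interval that needs it is given. Wilson intervals (95%) of shares cover the counting of peaks only.

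The conservative list was the main list because it requires both replicates. Of its 3009 peaks, 4 lie on unplaced sequences and entered only the counts of peaks and the replicate comparison. Transcription starts, exons, UTRs and genes came from Ensembl release 115 and sequence from the RefSeq dm6 assembly, and no peak ended beyond its arm in the reference. Transposable elements were dropped from the annotation. A summit was assigned to the protein-coding gene with the nearest annotated start. Where categories overlapped, a summit was counted as 5′ UTR before coding exon, 3′ UTR, non-coding exon and intron. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

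Replicate overlap was tested against 1000 draws from the ranked list of the same replicate. Shares on chromosome arms and near starts (500 bp) were compared between the conservative peaks and the ranked peaks that did not pass, with two-sided Fisher's exact tests. Motifs on either strand were counted within 50 bp of summits and in windows of the same width centred 500 bp to each side, with an exact McNemar test against each side and the larger p kept. A motif between its 2 flanks was given a p of 1. The interval of the difference came from 2000 bootstrap draws over peaks. Strong and weak peaks were the top and bottom 25% by signal. Gene lists were compared with 10000 random lists of the same size, matched in 20 bins on the length of genome nearest to each gene, with a two-sided permutation p. Benjamini-Hochberg adjustment was over 16 motifs, 11 motifs for strong against weak peaks, 7 arms and 12 lists, with a threshold of 0.05. Peaks and genes, not animals, are the units of these tests, so their p-values do not measure the spread between replicates.

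The design, the 12 gene lists and the alternatives were fixed before the data were examined. For 6 genes the symbol was updated to that of the annotation. The genes named are ato and da with their peaks, the nearest genes of the 10 peaks with the highest signal, the 5 genes nearest to the most peaks (ties broken by signal), and up to 4 genes per list with the strongest peaks. The achaete-scute genes, cato, amos, CG9630, the list members with absent peaks, the genes of the strongest absent peaks, the members of families chosen after the data were seen and the neighbouring genes of the strongest peaks and of list members were named after their values were seen. The alternatives were the pooled list, each replicate alone, the strongest 50% of peaks, merged peaks, main arms only, stricter overlaps, a shuffled background, equal numbers of peaks, other distances and windows, distal peaks only, and other ways of assigning and matching genes. Alternatives added after the data were seen were motifs in peaks near a start alone, the 124 absent peaks counted as passing for arms, starts and gene lists, the control motif without some of the words it matches, and every start within 500 bp of a summit counted for ribosomal protein genes and divergent starts.

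The motif, rank and gene list tests were tested on simulated data. In 3005 windows moved at random away from the summits, other peaks not excluded, 0 of 320 motif tests passed. A site planted in 5% of these windows was called in 20 of 20 draws. The windows were not placed at transcription starts, where most summits lie. The 0 of 320 therefore does not cover differences in base composition between starts and their flanks. With 751 windows a side and peaks in random order, 0 of 220 tests of strong against weak peaks passed. There a site planted in 5% was called in 19 of 20 draws. In both cases the planted site was CAGGTG, scored only as the core CACCTG, so recovery of CANNTG as a whole was not simulated. Of 200 random lists of 25 genes drawn from 13791, 3 had an unadjusted p under 0.05. Lists with 1.5 times the mean share of genes with a peak were called in 0 of 50 draws. Lists with 2 times that share were called in 50 of 50. The share was set in every draw, and the adjustment over the gene lists was not applied. These counts are therefore not detection rates for the adjusted tests. A list of that size shows only large excesses, and even an excess of 2 times may be missed after adjustment.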

Results

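Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where Atonal sits on the genome of fruit fly embryos. Atonal, encoded by ato, is a proneural basic helix-loop-helix (bHLH) factor that specifies chordotonal organs and the founder photoreceptors of the eye. The flies carried ato fused to enhanced GFP, whole embryos aged 0 to 18 h were collected, and the tagged protein was pulled down with an antibody against GFP. The series has 1 group, tagged embryos, with 2 biological replicates and no second condition. The comparisons the design allows are between the replicates, between peaks past the reproducibility threshold and the weaker ranked peaks, between summits and their flanks, and between gene lists and matched random lists. The files give peak positions and a signal per peak and no read counts, so the sequencing depth is unknown. A control was not analysed here.

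The question of the first comparison was how many sites passed and whether the replicates gave the same ones. The conservative list, which compares the replicates with each other, held 3009 peaks that formed 2880 distinct intervals and covered 0.899 Mb. Replicate 1 alone gave 2501 peaks and replicate 2 alone gave 1737, so the list of replicate 1 was 1.44 times as long. Of the peaks of replicate 1, 55.7% overlapped a peak of replicate 2 by at least 1 bp (1394 of 2501, 95% Wilson interval 53.8 to 57.7%). Of the peaks of replicate 2, 79.0% overlapped a peak of replicate 1 (1372 of 1737, 77.0 to 80.8%). Random draws of as many peaks from the ranked list of the same replicate gave medians of 1.60% and 1.84% (one-sided permutation p = 0.001 for each, the smallest that 1000 draws can give). The draws were not matched on signal or on distance to a start. They therefore do not show how far any strong peaks at starts would overlap. Across the 3009 peaks past the threshold, the log2 signals of the replicates had a Spearman rho of 0.688 and a Pearson r of 0.791. Selection by reproducible rank favours a high correlation among these. Across all 161563 ranked peaks, which were not so selected, rho was 0.258 and r was 0.310. These correlations are across peaks, which are not independent replicates, so no p is given. Of the conservative peaks, 1378 (45.8%) overlapped a peak in the list of each replicate, and 760 overlapped a peak in neither.

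The peaks lay mostly at the starts of genes. Of 3005 summits on the main chromosome arms, 2593 (86.3%, 95% Wilson interval 85.0 to 87.5%) were within 500 bp of an annotated transcription start. Among 156717 ranked peaks that did not pass, the share was 14.6%, and the log2 odds ratio was 5.20 (two-sided Fisher's exact test, p below the smallest value the computation can hold). The median distance from a summit to the nearest start was 49 bp, against 2669 bp for the ranked peaks that did not pass. Around protein-coding starts, 2448 summits lay within 500 bp, with a median position of -23 bp and quartiles of -54 and 14 bp, and 81.5% of them lay within 100 bp. The share near a start fell with peak strength, from 97.5% in the strongest 25% of peaks by signal to 73.8% in the weakest 25% (Fisher's exact test, two-sided, p = 8.05e-44). By annotation, 47.6% of summits were intergenic, 26.3% in a 5′ UTR, 14.7% in an intron, 5.16% in a non-coding exon, 4.96% in a coding exon and 1.30% in a 3′ UTR. Coding exons held 25.5% and introns 39.7% of the ranked peaks that did not pass. The 3005 peaks were nearest to 2622 protein-coding genes of the 13791 with a start of their own.

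**Figure D1:**
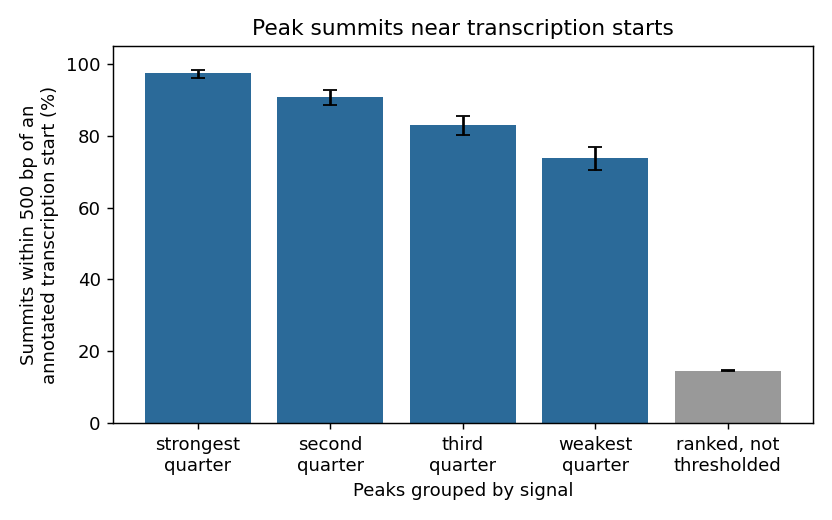
Share of peak summits within 500 bp of an annotated transcription start (y axis, percent), for the conservative peaks in 4 groups from the strongest to the weakest 25% by signal and for ranked peaks that did not pass (x axis). Bars are shares and error bars 95% Wilson intervals; the share goes from 97.5% to 73.8% over the conservative peaks and is 14.6% for the other ranked peaks.

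The strongest peak stood apart from this picture, in an intron of org-1, which encodes a T-box transcription factor. It covers X 8452229 to 8452506 (dm6), had a signal of 954.9, and its summit at 8452366 lies 2503 bp downstream of the nearest org-1 start. The 41 bases around its summit, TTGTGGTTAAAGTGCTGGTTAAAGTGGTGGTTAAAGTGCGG (X 8452346 to 8452386), repeat the unit TTAAAGTG. The other 9 of the 10 strongest peaks had summits at -130 to -14 bp from a protein-coding start, and all 10 overlapped a peak in the list of each replicate. They were nearest to Ube3a, a ubiquitin ligase gene, with a signal of 810.0 (3L 11210470 to 11210792), Fit2, a kindlin gene, with 546.3 (3L 17024162 to 17024418), and RpL32, a ribosomal protein gene, with 526.7 (3R 30046089 to 30046401). The rest were milt, which encodes an adaptor for mitochondrial transport, at 524.4, MESK2 at 508.2, Rpn6, a subunit of the proteasome, at 480.2, Capr at 476.2, Snx27, a sorting nexin gene, at 474.6 and CG11030 at 470.5. Of these summits, 4 were also within 500 bp of another coding start, those of Ube3a (CG7600), RpL32 (CG7943), MESK2 (TAF1C-like) and Rpn6 (ave). Within 50 bp of these 10 summits an E-box was found at 2 sites, CATCTG at Fit2 and CAGCTG at Snx27.

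At the genes of Atonal itself and of its bHLH partner Daughterless the peaks were weak. A single peak was nearest to ato (FBgn0010433, 3R 8278052 to 8279274, plus strand), at 3R 8274843 to 8275178, in intergenic sequence, with its summit at -3041 bp from the start. Its signal was 59.1, rank 2617 of 3009, and CAGTTG lay within 50 bp of the summit. A single peak was nearest to da (FBgn0267821, 2L 10388105 to 10393228), at 2L 10390887 to 10391222, in a coding exon with its summit 2950 bp past a start, with a signal of 57.4 and rank 2701 and no E-box within 50 bp. Neither peak overlapped a peak in the list of either replicate alone. The 38 ranked peaks around ato had a median signal of 32.2, higher than at 99.4% of protein-coding loci of the same span.

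**Figure D2:**
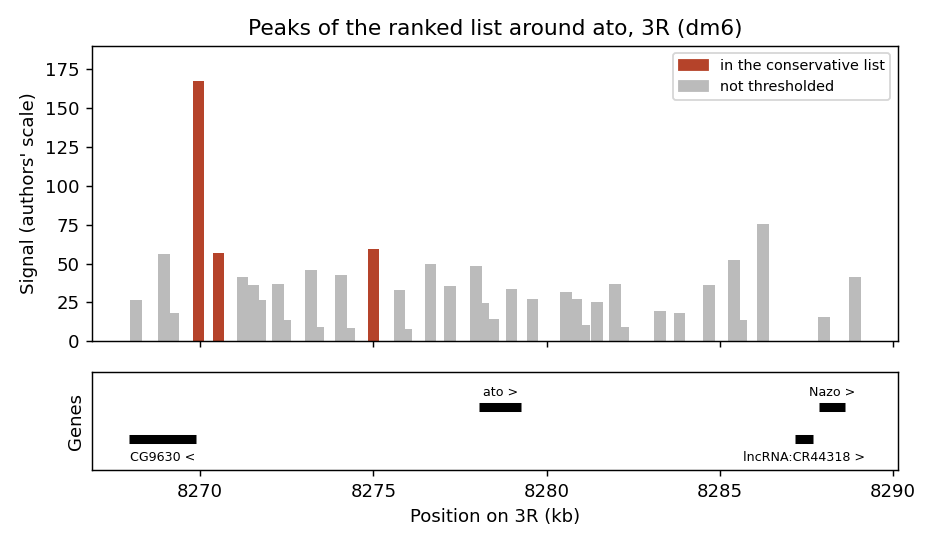
Map of 3R around ato (x axis, kb, dm6) with the signal of each ranked peak on the authors' scale (upper panel, y axis) and annotated genes with their direction (lower panel). Red bars are in the conservative list and grey bars did not pass; of the 3 red peaks upstream of ato, the one nearest to it has a signal of 59.1, and those farther out have 56.9 and, at the start of CG9630, 167.2.

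EcR, which encodes the ecdysone receptor, was nearest to 9 peaks on 2R, more than any other gene, with signals from 4.29 to 236.2. Of these, 4 overlapped a peak in the list of each replicate, at 2R 6152559 to 6152720, 6151265 to 6151600, 6162376 to 6162711 and 6153340 to 6153675, in introns and non-coding exons. Eip75B, an ecdysone-induced nuclear receptor gene on 3L, was nearest to 5 peaks with signals of 22.6 to 70.7, and none of them overlapped a peak of either replicate alone. CG8036, Sema1a, which encodes a semaphorin, and inc each had 4. CG8036 and its peaks lie on 3R, Sema1a on 2L and inc on X, and 3 further genes tied with them were not named because their peaks were weaker. The length of genome nearest to a gene differs, from 4.07 kb for CG8036 to 50.05 kb for EcR and 112.2 kb for Eip75B. Some of the peaks counted for EcR, Eip75B, Sema1a and inc overlap each other. All inc summits except that of the peak at X 1517525 to 1517860 were also within 500 bp of a coding start of another gene.

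No excess of E-boxes (CANNTG), the sites of bHLH dimers, was detected at summits over the sequence beside them. Within 50 bp of the summit 38.7% of 3005 peaks held CANNTG, against 39.5% in windows centred 500 bp toward lower and 38.9% toward higher coordinates. The summit share minus the mean of the flanks was -0.47 percentage points (95% bootstrap interval -2.61 to 1.58, exact McNemar test, two-sided, larger p = 0.916, Benjamini-Hochberg adjusted p = 1 over 16 motifs). Of the E-box cores, CAGCTG was more frequent at summits, at 9.28% against 5.79% and 4.76% (adjusted exact p = 2.46e-06). CAACTG was at 7.45% against 5.66% and 6.06% and did not pass (adjusted exact p = 0.0903). Over the 412 peaks more than 500 bp from a start CAACTG was at 9.71% against 5.10% and 4.37%, without passing (adjusted exact p = 0.116). CAAATG (6.46% against 9.08% and 8.65%, adjusted exact p = 0.00584), CACCTG (3.49% against 5.39% and 5.02%, adjusted exact p = 0.0129) and CATATG (1.76% against 3.03% and 3.23%, adjusted exact p = 0.00721) were less frequent. In a scan of all 2080 words of 6 bases, chosen after the data were seen, 248 were more frequent at summits and 323 less frequent past the threshold. Calls in both directions were thus common among these words. The words can share bases, as 7 of the 10 largest excesses held TATCG, CGATA or ATCGAT, so their calls are not independent. They were also adjusted over another number of tests than the 16 motifs. The scan therefore does not decide whether the calls of the cores are particular to E-boxes. The Ato-type site WCAKGTG was found at 3.19% of summits and in 4.09% and 4.43% of flanks (adjusted exact p = 0.170), and the Sc-type site GCAGSTG at 4.09%, 5.12% and 4.23% (adjusted exact p = 1). The Zelda site CAGGTAG was at 0.433% of summits (adjusted exact p = 0.367) and GAGAGAG at 2.56% (adjusted exact p = 0.247). The control fixed beforehand, CNANTG, takes in the E-boxes CAANTG and the word CGATTG, so it does not measure base composition alone. It was more frequent at summits, at 62.0% against 54.1% and 51.8% (adjusted exact p = 1.37e-08), a difference of 9.02 points. CGATTG, read as CAATCG on the other strand, was at 14.8% of summits and in 4.79% and 4.33% of flanks. In alternatives chosen after the data were seen, the difference was 11.6 points without CAANTG (exact McNemar test, p = 1.90e-17) and 5.39 points without CGATTG as well (exact p = 0.000152). The excess of CAGCTG did not pass in windows of 25 bp each side (1.498 points, adjusted exact p = 0.162) and over peaks more than 500 bp from a start (2.06 points, adjusted exact p = 0.690, 412 peaks). The lower shares of CATATG, CAAATG and CACCTG did not pass under 7, 5 and 2 of the 9 alternatives, but every difference stayed negative. Where the call was lost, CATATG ranged from -2.18 to -0.599 points, against -1.36 in the main list. CAAATG then ranged from -2.40 to -1.08 against -2.41, and CACCTG was -1.46 and -0.850 against -1.71. In the list of replicate 2 alone CACCTG was -3.52 points (adjusted exact p = 9.21e-05). CACGTG was at 1.73% of summits and in 1.198% and 0.932% of flanks (adjusted exact p = 0.202), and it passed in the list of replicate 1 alone, at 2.20% against 1.12% and 1.0004% (adjusted exact p = 0.0144). WCAKGTG was less frequent at summits and passed within 100 bp (-1.91 points, adjusted exact p = 0.0151) and in the list of replicate 2 alone (-1.92 points, 0.0428). GAGAGAG was more frequent and passed within 100 bp, against flanks at 1000 bp and over peaks more than 500 bp from a start (adjusted exact p = 0.000433, 0.0197 and 0.0131). CNANTG did not pass over the 412 peaks more than 500 bp from a start (adjusted exact p = 0.168). Its difference there was 8.86 points, close to the 9.02 points over all peaks.

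**Figure D3:**
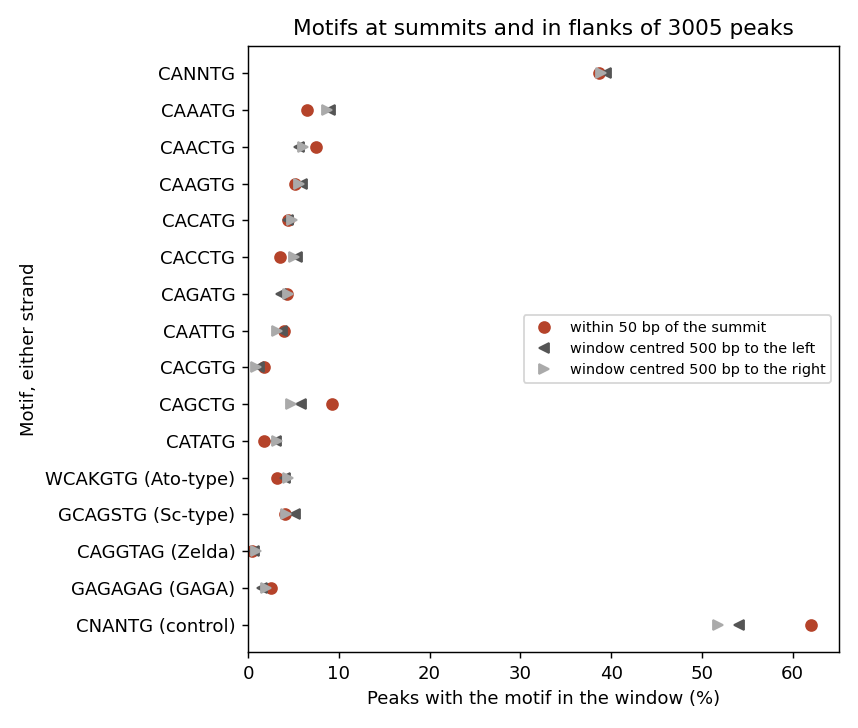
Share of the 3005 conservative peaks on the main arms with each motif on either strand (x axis, percent) within 50 bp of the summit (circles) and in windows of the same width centred 500 bp to either side (triangles). CANNTG has 38.7% at summits and 39.5% and 38.9% in the flanks, and CAGCTG 9.28% against 5.79% and 4.76%.

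Strong peaks held fewer E-boxes than weak ones. Of the strongest 25% of peaks by signal 31.7% had CANNTG within 50 bp (238 of 751), against 43.5% of the weakest 25% (327 of 751, Fisher's exact test, two-sided, adjusted exact p = 2.94e-05 over 11 motifs). Of the cores, CAAATG passed as well, at 4.53% against 7.99% (adjusted exact p = 0.0410). CAGCTG was at 8.12% and 8.26% (adjusted exact p = 1). In the list of replicate 2 alone the difference in CANNTG was -7.91 points and did not pass (adjusted exact p = 0.209). Strong and weak peaks were compared without their flanks, and they also lay in different kinds of sequence. Of the strongest 25%, 97.5% were near a start and 0.266% in coding exons, against 73.8% and 14.5% of the weakest 25%. The difference in E-boxes was not separated from this.

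Ribosomal protein genes had more peaks than matched random lists, while the lists of genes linked to Atonal and to sensory neurons did not pass the threshold. Of 81 ribosomal protein genes in the annotation, 36 were nearest to a peak, against a mean of 13.9 in 10000 lists matched on the length of genome nearest to each gene (adjusted permutation p = 0.0012 over 12 lists from a permutation p of 0.0002, the smallest the draws can give). RpL32 led with 526.7, then RpS2 with 338.9, RpS7 with 211.3 and RpL11 with 208.6. Of 15 genes associated with atonal, 4 had a peak against 3.13 expected (adjusted permutation p = 0.923): lqf at 129.2, rho, a protease gene of EGF receptor signalling, at 115.5, phyl at 59.7 and ato. Of 13 proneural bHLH genes, 3 did against 2.67 (adjusted permutation p = 1), with emc, an inhibitor of bHLH factors, at 136.8, ato and da. The achaete-scute genes ac, sc, l(1)sc and ase, and cato and amos, had none. The sensory cilium list had 3 of 24 against 4.90 (adjusted permutation p = 0.662), which were rempA, a ciliary transport gene, at 81.6, nompC, a mechanotransduction channel gene, at 79.8 and IFT52 at 67.0. Of 28 neural precursor and neuron genes, 4 had a peak against 6.58 (adjusted permutation p = 0.618), namely insc at 87.8, elav at 81.3, Dr at 68.3 and cpo at 59.2. The summits at IFT52 and insc were also within 500 bp of a coding start of COX5B and of sktl, respectively. The summits assigned to nompC and cpo lay 15466 and 10178 bp from the nearest start of the gene. With only summits within 5000 bp of a start, the sensory cilium list had 2 genes against 4.75. The neural precursor and neuron list then had 3 against 5.87 (adjusted permutation p = 0.523 for each). Like those of ato and da, the peaks of phyl, IFT52, insc, Dr and cpo overlapped no peak in the list of either replicate alone. The Notch pathway list had 8 of 25 against 5.15 (adjusted permutation p = 0.618), with mib1 at 213.4, Su(H), its transcription factor, at 167.8, numb at 118.5 and kuz at 104.8. It had 7 against 4.31 in the list of replicate 1 alone and 4 against 3.17 in that of replicate 2 alone, without passing.

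The EGF receptor pathway was the only developmental list past the threshold, with 9 of 17 genes against 3.63 expected (adjusted permutation p = 0.0344). Its strongest peaks were at rho, Egfr (108.5), edl (106.6) and aop (96.0). The call was lost under 4 of the 9 alternatives tried. These were the list of replicate 1 alone, with 5 genes against 2.96 (adjusted permutation p = 0.583), and that of replicate 2 alone, with 4 against 2.02 (0.791). The others were the strongest 50% of peaks, with 5 against 1.76 (adjusted permutation p = 0.210), and matching on the number of ranked peaks, with 9 against 4.06 (0.0960). Retinal determination and eye genes had 7 of 20 against 4.51 (adjusted permutation p = 0.618), with eyg (99.6), hth (95.3), B-H1 (72.5) and tsh (70.0) leading. Segmentation and Hox genes had 9 of 28 against 6.52 (adjusted permutation p = 0.618), with Ubx (130.4), abd-A (99.7), odd (96.0) and opa (90.2) leading. In the list of replicate 1 alone that list passed, with 13 of 28 against 5.33 (adjusted permutation p = 0.0064). In that of replicate 2 alone it had 5 against 3.56 and did not pass (adjusted permutation p = 0.975). Mesoderm and muscle genes had 5 of 28 against 6.03 (adjusted permutation p = 0.923), with Mef2 (129.2), lbe (103.9), mbc (103.3) and how (73.5) leading. The summits at Egfr and mbc were also within 500 bp of a coding start of CG30289 and of Nup98-96, respectively. The summits of the strongest peaks assigned to hth, tsh and Ubx lay 78311, 26711 and 18588 bp from the nearest start of the gene. The peaks of B-H1, tsh and how overlapped no peak in the list of either replicate alone. Endoderm, hemocyte and trachea genes had 7 of 22 against 4.94 (adjusted permutation p = 0.618), with GATAe (113.3), rib (97.1), ush (94.4) and pnr (80.4) leading. They had 8 against 3.98 in the list of replicate 1 alone and 3 against 2.72 in that of replicate 2 alone, without passing. None of the 111 histone genes, 88 of core histones and 23 of H1, had a peak against 12.6 expected (adjusted permutation p = 0.0012), and with matching on ranked peaks the difference was -2.20 (adjusted permutation p = 0.688). A ranked peak near the start of His3:CG31613, with a signal of 99.8, passed the same rate and is not in the list, as did peaks of Rfx, Ras85D and Tm1. The histone genes are near-identical copies that share reads, so their value is uncertain.

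**Figure D4:**
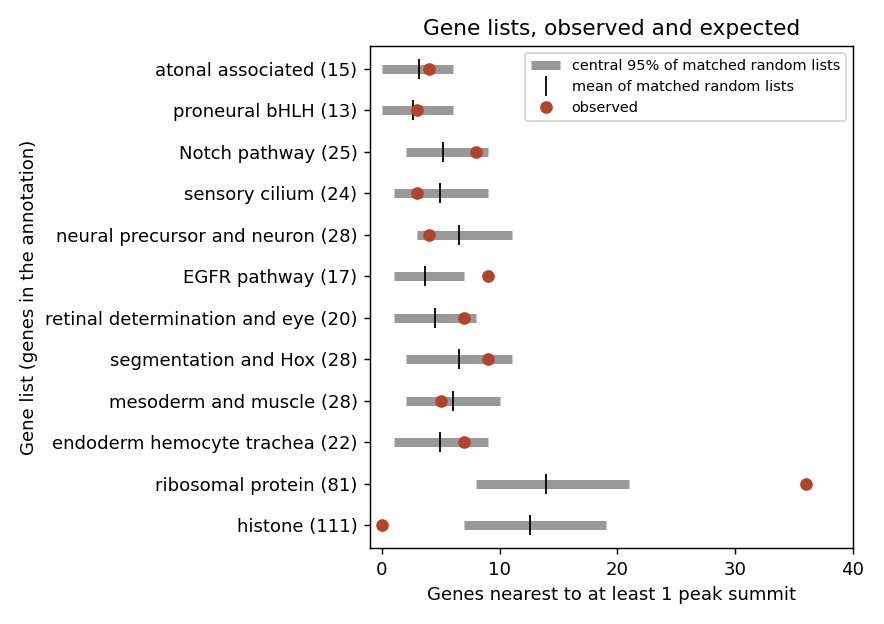
Number of genes of each fixed list nearest to at least 1 peak summit (circles, x axis) with the mean (tick) and the central 95% range (grey bar) of 10000 matched random lists, and the genes of each list in the annotation in brackets (y axis). Ribosomal protein genes (36) and EGF receptor pathway genes (9) lie above their range, and histone genes (0) below it.

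By chromosome arm, 2R held more of the peaks than of the ranked peaks that did not pass, at 22.7% (681 peaks) against 18.6% (log2 odds ratio 0.36, Fisher's exact test, two-sided, adjusted exact p = 1.89e-07 over 7 arms). 3R held fewer, at 23.3% against 25.2% (adjusted exact p = 0.0305), and the Y none of the 3005 against 0.206% (adjusted exact p = 0.0124). The X held 16.2% against 17.7% (adjusted exact p = 0.0524), and the fourth chromosome 11 peaks, 0.366% against 0.202% (adjusted exact p = 0.0867). 3L held 19.2% against 19.95% (adjusted exact p = 0.389) and 2L 18.3% against 18.1% (adjusted exact p = 0.774). In the list of replicate 1, that of replicate 2 and among the strongest 50% of peaks, 3L held fewer peaks and passed (adjusted exact p = 0.00476, 0.0141 and 0.00139). The Y again held no peak in any of them and did not pass (adjusted exact p = 0.899, 0.380 and 0.191). With the peaks that pass the same rate but are not in the list counted in, an alternative chosen after the data were seen, 3R held 24.3% of 3118 peaks and did not pass (adjusted exact p = 0.294). The X then passed, at 15.8% against 17.7% (adjusted exact p = 0.00967). The call for 3R was also lost in the list of replicate 2 and among the strongest 50% (adjusted exact p = 0.219 and 0.199). Its log2 odds ratios there, -0.131 and -0.139, were close to the -0.155 of the main list, which holds more peaks. The fourth chromosome passed in the list of replicate 1 (log2 odds ratio 1.13, adjusted exact p = 0.0242).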

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

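Peaks outside the thresholded lists are given here because they carry signal that no planned comparison of those lists used, and their examination was chosen after they had been seen. In the ranked list that pairs the replicates, 124 peaks pass the same reproducibility rate as the conservative list and are absent from it. They include peaks as strong as those nearest to osa (465.7), kibra (460.1), Bicra (387.5) and rump (340.9). Of the 113 on the main arms, 53.1% lie on 3R and 72.6% within 500 bp of a start, and the median signal of the 124 is 93.6 against 88.6 in the conservative list. Of the 124, 110 overlap peaks that are absent in the same way from the pooled list, 78 from that of replicate 1 and 69 from that of replicate 2, and 0 overlap a peak that any of the 4 thresholded lists holds. Members of the fixed gene lists with a peak among the 124 and none in the conservative list are Ras85D (104.3), His3:CG31613 (99.8), Tm1 (72.2) and Rfx (54.6). Each thresholded list was also derived from a further file that the ranked lists do not name, per the accompanying text files, and its nature is not given in the sources used here. Whether that file removed regions was not tested, so the absence of these peaks does not show that the sites failed.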

How the results depend on the processing

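The alternatives that keep peaks near a start for motifs, count in the absent peaks, count every start or drop words from CNANTG were chosen after the data were seen, and the others before. The share of summits near a start stayed between 80.1 and 94.1% under every alternative tried. The replicates overlapped more than random draws or shuffled peaks under every alternative, none of which was matched on signal or distance to a start. The replicate comparisons cannot be made without either replicate. The ribosomal protein list stayed above its random lists, and 2R above the ranked peaks that did not pass, under all alternatives tried. The count of 3009 peaks became 1504 for the strongest 50% by signal, by construction, and 1737 to 2501 in the list of either replicate alone. Over the strongest 50% of ranked peaks, rho between replicates was 0.0714. These were selected on the signal of both replicates combined, which can itself lower rho. The value therefore does not measure how well the replicates match among strong peaks. For the changes that follow, the cause was not tested. The E-box difference between summits and flanks turned positive in the pooled list (0.687 points) and over peaks more than 500 bp from a start (4.73 points), without passing. It was more negative among the strongest 50% (-3.66 points, bootstrap interval -6.86 to -0.63), against flanks at 1000 bp (-2.41, -4.53 to -0.37) and without replicate 1 (-2.41, -5.23 to 0.46), and did not pass there either. The difference between strong and weak peaks in CANNTG was -9.78 to -7.91 points in the list of either replicate, and the latter, without replicate 1, did not pass. It was -5.79 points between the stronger and weaker 50% and passed. With matching on ranked peaks 1 gene list passed, against 3.

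The log2 odds ratio of the X ranged from -0.0069 to 0.14 over the lists of either replicate and was 0.065 among the strongest 50%, and that of 2L from -0.083 to 0.023 and -0.025. GAGAGAG ranged from -0.610 to 1.16 points over those lists and was -0.167 among the strongest 50%. Over peaks more than 500 bp from a start, WCAKGTG turned to 0.121, GCAGSTG to 0.607 and CACGTG to -0.607 points. Genes with a peak minus the expected number changed sign without passing in 5 lists. Over the lists of either replicate they ranged from -1.57 to 0.186 for atonal-associated, -1.23 to 0.333 for proneural and -2.42 to 1.36 for eye genes. In the pooled list they were -0.336 for atonal-associated and 0.377 for mesoderm and muscle genes. Among the strongest 50% they were -0.462 for proneural and -0.157 for eye genes, and with gene bodies -1.47 for proneural and 1.17 for sensory cilium genes. The unknown depth limits what an absent peak can show.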

Other observations

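The gene families, the scan of all 6-base words, the TATCGA shares by strength and at starts, the divergent starts, the counts over every start, the org-1 repeat and the 10 kb steps described here were chosen after the data had been seen, and the 5 tests of the explanations weighed were written before their results. Of 19 gene families picked by symbol, all tested against 10000 matched random lists after their counts had been seen, 3 were nearest to peaks more often than their random lists, 6 less often, and 10 did not pass. Proteasome genes had a peak in 16 of 48 cases against 8.18 expected (adjusted permutation p = 0.0209 over the 19 families), led by Rpn6 (480.2), Prosalpha7 (370.3) and Rpn10 (298.8). Mitochondrial ribosomal protein genes had 23 of 71 against 10.9 (adjusted permutation p = 0.0019), with mRpL4 at 349.7 and mRpL30 at 289.6, and Rab GTPase genes, which direct vesicle traffic, 12 of 31 against 6.04 (adjusted permutation p = 0.0418), with Rab30 at 334.0. Nucleoporin genes did not pass, with 8 of 21 against 3.75 (adjusted permutation p = 0.0825), and neither did translation initiation factors (12 of 43 against 8.01, 0.280) or respiratory chain and ATP synthase genes (17 of 79 against 13.8, 0.543). The other 7 that did not pass were vacuolar ATPase, Mediator, tetraspanin, heat shock, spliceosomal, basal transcription factor and actin-related genes (adjusted permutation p from 0.131 to 1).

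The 6 families below their random lists follow, with no test of them as a group. Cuticle protein genes had a peak in 3 of 70 cases against 13.06 (adjusted permutation p = 0.00253), cytochrome P450 genes 4 of 83 against 16.2 (0.00228) and odorant-binding protein genes 1 of 49 against 8.48 (0.00651). Odorant receptor genes had 0 of 58 against 11.5, gustatory receptor genes 1 of 60, Gr89a, against 10.9, and ionotropic receptor genes 1 of 60, Ir56b, against 11.98 (adjusted permutation p = 0.00127 for each of these 3). Members of some of these families lie side by side, so they are not independent draws. With each summit counted only for the gene with the nearest start, 21.8% of 3736 genes with a start within 500 bp of a divergent start were nearest to a peak within 500 bp, against 14.7% of the other 10055 (Fisher's exact test, two-sided, p = 6.11e-22). With every start within 500 bp of a summit counted the shares were 38.7% and 15.2%, and then 1 summit can count for both genes of a pair.

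TATCGA, part of the sites of the promoter factor DREF and the boundary factor BEAF-32, had the largest excess at summits of 2080 words of 6 bases. It was within 50 bp of 41.9% of summits (1259 of 3005, 95% Wilson interval 40.1 to 43.7%), against 5.16% and 3.83% of flanks. Its share was 72.3% in the strongest 25% of peaks, then 51.5%, 27.0% and 16.8% in the weakest, and it was 44.5% in the list of replicate 1 and 56.0% in that of replicate 2. At the starts of genes without a nearest peak it was 11.8% (1316 of 11169), against 50.4% at starts of genes nearest to a peak within 500 bp (1157 of 2294). A single start per gene was used, with the window centred at -23 bp, the median position of the summits. As 2972 genes had a start within 500 bp of a summit, the genes without a nearest peak can include some with a summit near their start. At the 412 summits more than 500 bp from a start, GAGAGC (13.8% against 4.37% and 3.88%, adjusted exact p = 5.27e-04) and GAGCGA (12.9% against 3.40% and 2.91%, adjusted exact p = 1.41e-04) had the largest excesses. At these summits CGATAG passed as well, at 9.71% against 1.21% and 3.40% (adjusted exact p = 0.0159). TATCGA was at 11.7% of them against 5.34% and 3.64% and did not pass among the 2080 words (adjusted exact p = 0.0785). The strongest peak, in org-1, holds 5 copies of TTAAAGTG, and 2 other conservative peaks hold 2 or more.

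The first pattern weighed is that the strongest peaks lay at transcription starts while E-boxes were no more frequent at summits than in flanks. Promoter and boundary factors at these sites may account for part of it, with CGATA 41.2 percentage points more frequent at summits than in flanks (53.7% against 12.8% and 12.2%). Over the 412 peaks more than 500 bp from a start CGATA was at 21.8% against 10.4% and 12.4%. Signal collected at highly transcribed open promoters whatever the factor stays possible, as 43.2% of ribosomal protein genes were nearest to a peak within 500 bp of a start against 16.5% of the other protein-coding genes (Fisher's exact test, two-sided, p = 1.52e-08), or 44.4% against 21.4% with every such start counted, though this nearly restates the list result (36 of 81). Of the families above, mitochondrial ribosomal protein (23 of 71) and proteasome genes (16 of 48) passed, while translation initiation factors (12 of 43) and respiratory chain genes (17 of 79) did not, which excludes nothing since smaller excesses can be missed. Whether E-boxes mark peaks away from starts stays open, because the excess there was 4.73 points with an interval of -0.73 to 10.1 (exact McNemar test, p = 0.237), and recruitment of Atonal by other proteins was not tested.

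The second pattern is the longer list in replicate 1. Of its 1107 peaks without a peak in replicate 2, 96.7% overlapped the ranked list of replicate 2, at a median signal percentile of 96.8 there. The same sites missing the threshold in replicate 2 would give such values. The ranked list of replicate 2 holds 141198 peaks over 38.9 Mb, so part of the overlap can arise by position alone. No chance level was computed, and the percentile is that of the strongest overlapping peak. Depth could set such a difference in list length and is unknown here, and no biological explanation was tested.

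The third pattern is the weak peak nearest to ato, the closest of 3 conservative peaks upstream of it. Ranked peaks around ato had a median signal higher than at 99.4% of 13613 loci of the same span. In steps of 10 kb, the percentile of the median signal among 13251 steps was 92.5, 69.6 and 91.1 from 80 to 50 kb below the middle of ato, 97.6 to 99.4 from there up to it, 94.3 and 88.8 in the next steps, 99.6 and 99.1 from 20 to 40 kb above it, 94.4 and 77.3 to 60 kb, and 64.2 and 75.6 to 80 kb. Extra copies of a genomic fragment with the tagged gene may raise the signal over the whole locus, in which case the peak does not show binding of Atonal at its own gene. Such binding was not excluded, and no biological explanation was tested.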
